A study of Mus musculus with 7 samples.

How the data were processed

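RNA sequencing was applied to the prefrontal cortex of male C57BL/6J mice aged 8 weeks, 3 wild-type (WT) and 4 of the genotype that the labels call hDISC1AA/+. Per the labels' protocols, total RNA was taken from frozen tissue with Trizol and made into libraries with a NEBNext Ultra RNA kit, which the labels do not describe as strand-specific. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.1.0, HTSeq 0.6.1, DESeq2 1.26.0 and the mouse genome build mm10, with no role or order. The annotation version, the strand setting of the read counting and the treatment of reads that match several places are not given in the sources used here. The labels number the samples but do not say that each came from a separate mouse. The p-values of single genes and of list levels per library therefore measure the spread between these 7 samples, which may in part be technical.

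The table deposited by the authors holds 1 value per gene and sample. These values are a signal proportional to reads and not raw counts: within each column every deposited value above 0 was a whole multiple of 1 smallest step, within a tolerance of 0.01 reads, for 100% of the values in all 7 columns. The authors therefore deposited gene counts divided by 1 size factor per library, and dividing by the step gave back the whole reads. The main test had been planned on raw counts before the data were examined (edgeR's quasi-likelihood test). Because the unit was a normalized one, limma was used as the main test and the planned edgeR test was run on the recovered reads as an alternative. In the text, "normalized count" means the deposited value.

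The recovered libraries held 33512557 to 63845254 reads assigned to genes, with WT replicate 1 the deepest and the other 6 at 36005116 or fewer. All 7 columns of the table were used. Of these, 6 carry a title from the labels, 3 WT (replicates 1 to 3) and 3 hDISC1AA/+ (replicates 1, 3 and 4). The remaining column has the hDISC1AA/+ ending but a number found in no title, and is called the unnumbered hDISC1AA/+ library. The title of WT replicate 1 has another form than the names of the other 6 columns, and the labels give no reason for it. Replicate numbers follow the order of the records and pair nothing between the groups. No 2 libraries were copies of each other: over genes, the chi-square per degree of freedom between pairs was 11.5 to 177. For 3 genes the identifier and the values stood on separate lines, and these were left out; they held 0.012% to 0.0169% of the values per library. The table has 43626 gene identifiers, of which 42459 matched the GENCODE M21 annotation of GRCm38 (the assembly that mm10 names) and 1167 did not; symbols, gene types and coordinates come from that annotation.

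Genes with a normalized count of at least 10 in at least 3 libraries were tested (17670 genes). The test was limma's moderated linear model with an intensity trend and robust variances on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, as hDISC1AA/+ minus WT, and understate the change of genes with low counts; intervals are 95% confidence intervals of limma. Before the data were examined, 36 gene lists were fixed (proteins that act with DISC1, Wnt targets, polarity, axon guidance, synaptic and channel genes, neuronal and glial cell types, neighbouring tissues, blood, and stress, immune and energy metabolism genes). Lists were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation. In its preset form camera sets a list's genes against other genes. Its p-value does not measure how the level of a list varies between samples. Beside them was run fry, which asks whether a list's genes move on balance one way. The mean log2 level of each list per library was compared by an exact permutation test over the 35 ways to divide 7 libraries into 3 and 4, whose smallest p is 0.0286. The rule for named genes was fixed beforehand too: Disc1 first, then genes past the threshold and, since fewer than 20 passed, those with the smallest unadjusted p up to 20, and up to 3 members with the smallest p for each list described. Unnamed gene models are named only among the first 5 of a direction.

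The calculations were tested on simulated counts for the comparison of hDISC1AA/+ with WT, drawn from the real means, dispersions and library sizes, with 200 genes changed and 77 genes of 1 list raised by 0.3 on the log2 scale. The changed genes were drawn only from those above a minimum mean count. Reads were drawn independently between genes, without libraries that stand apart, so the rates in the real data may differ. Of the changed genes, limma called 13.4% of 67 at 1.5-fold, 70.1% of 67 at 2-fold and 95.5% of 66 at 4-fold among 17365 genes, and of its 128 calls 119 were of changed genes, 3 of genes in the raised list and 6 were false. The alternatives were other scaling factors, filters, pseudocounts and thresholds, thinning of all libraries to the depth of the smallest, leaving out each library, DESeq2, limma-voom with and without sample quality weights, edgeR with and without robust dispersions, 1 surrogate variable from sva, and camera without blood, mitochondrial and ribosomal protein genes. Chosen after seeing the data were TMM factors, pseudocounts of 0.5 and 8, limma array weights, the robust edgeR test in place of the main test, leaving out WT replicate 1 and hDISC1AA/+ replicate 1 together, and a correction of each library for smooth trends in GC content and transcript length (17543 genes, 99.3% of those tested, had both values). R 4.3.3 was used with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.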

Results

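The transcriptome of the prefrontal cortex was compared between 3 WT and 4 hDISC1AA/+ libraries. DISC1 is a scaffold protein of developing and adult neurons, and the study concerns its phosphorylation and the polarity of cortical neurons. The comparison asks which transcripts differ in the adult cortex of mice with 1 altered allele. The libraries held 63845254, 34572903 and 34682070 reads assigned to genes in WT replicates 1 to 3. They held 33512557, 35006151 and 36005116 in hDISC1AA/+ replicates 1, 3 and 4 and 34591153 in the unnumbered hDISC1AA/+ library, with reads for 22929 to 23812 genes. All values below are the authors' normalized counts (reads divided by 1 size factor per library).

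The main differences between libraries did not follow genotype. The first principal component, with 38.7% of the variance, set WT replicate 1 (-70.4) apart from the other 6 libraries (-17.4 to 26.3). The second, with 31% of the variance, set hDISC1AA/+ replicate 1 (66.4) apart from the rest (-27.3 to 0.309). Mitochondrially encoded transcripts took 1.94% of the reads in hDISC1AA/+ replicate 1 and 5.14% to 6.94% in the other 6. In hDISC1AA/+ replicate 1, GC content and transcript length accounted for 0.358 of the variance of the genes' deviations from the mean of the 7 libraries, against 0.119 or less in the others.

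**Figure D1:**
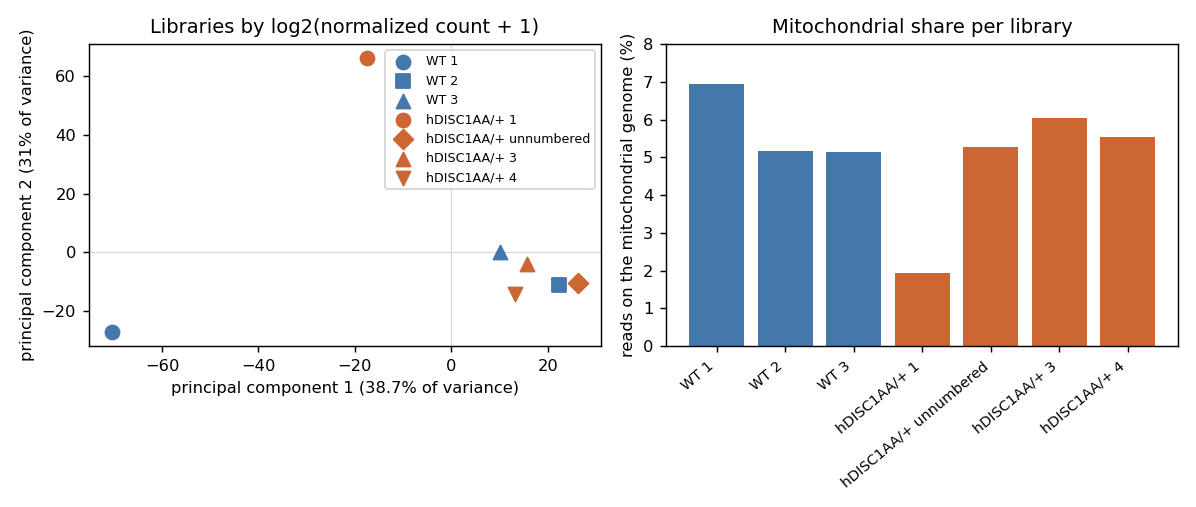
Left, the 7 libraries on the first 2 principal components of log2(normalized count + 1), which hold 38.7% and 31% of the variance; blue is WT and orange is hDISC1AA/+. Right, the percent of reads on the mitochondrial genome in each library. WT replicate 1 and hDISC1AA/+ replicate 1 lie apart from the other 5 libraries, which mix both genotypes.

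Disc1 itself did not differ detectably between the genotypes. Disc1 (ENSMUSG00000043051, chromosome 8, 125054195 to 125261858 of GRCm38, plus strand) had normalized counts of 46.9, 72.0 and 109 in WT (mean 76.0 ± 31.3 SD, n = 3). In hDISC1AA/+ it had 60.3 in replicate 1, 81.0 in the unnumbered library, 80.2 in replicate 3 and 85.4 in replicate 4 (mean 76.7 ± 11.2 SD, n = 4). The log2 fold change was 0.08 (95% CI -0.59 to 0.75; limma adjusted p = 0.998), and the exact permutation test over 35 splits gave p = 0.8, two-sided. The sign depended on WT replicate 1, without which the log2 fold change was -0.22. These are reads assigned to mouse Disc1 as a whole gene. They cannot separate the altered allele from the other one, and an antisense gene, Gm16237, overlaps it. The sources used here do not state whether the altered allele holds human sequence. Reads from such sequence might not be counted as mouse Disc1, in which case these values would understate Disc1 in hDISC1AA/+. The list of 18 measured genes next to Disc1 on the chromosome, 11 higher and 7 lower, did not pass camera (adjusted p = 0.655).

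No gene passed the threshold between hDISC1AA/+ and WT. Of 17670 genes tested by limma, 0 had an adjusted p under 0.05 (the smallest was 0.974), and 431 genes (2.44%) had an unadjusted p under 0.05, where 884 are expected with no differences. On the recovered reads, edgeR called 0 of 17540 genes, with 452 at an unadjusted p under 0.05, and DESeq2 called 0 of 28315, with 604. With weighted libraries the counts lay above 884: 1391 with limma-voom sample quality weights and 1823 with limma array weights, and again 0 genes passed. The array weights were lowest for WT replicate 1 (0.244) and hDISC1AA/+ replicate 1 (0.279). They were highest for WT replicate 3 (5.23, against 0.942 for WT replicate 2), so the WT side of that fit rested mostly on 1 library. The count thus depended on the weights, and the count under 884 in the main test does not show less difference than chance gives. The normalized counts of the groups did not overlap for 890 genes (5.04%), where chance gives 5.71%. For 13669 genes (77.4%) the 95% CI of the fold change lay within 2-fold in either direction, and for 9550 genes (54%) within 1.5-fold. For the other genes a change of 2-fold was not excluded at this number of libraries.

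The 20 genes with the smallest unadjusted p comprised 11 higher and 9 lower in hDISC1AA/+, and none passed (all with a limma adjusted p of 0.974). In all 20 the groups did not overlap, which with 17670 genes is within what chance gives. Of those lower in hDISC1AA/+, Fzd3, a Frizzled receptor needed for axon guidance (chromosome 14, 65192449 to 65262463), had 1755 ± 263 normalized counts in WT and 1113 ± 270 in hDISC1AA/+ (SD; log2 fold change -0.68, 95% CI -1.12 to -0.24). Tenm1, a teneurin adhesion protein on the X chromosome, had 2191 ± 318 and 1535 ± 244 (log2 fold change -0.52). Stxbp5l, a tomosyn that restrains vesicle fusion, had 2768 ± 0.412 and 2041 ± 331 (log2 fold change -0.45). Cdh6, a cadherin, had 487.6 ± 73.2 and 335.2 ± 38.8 (log2 fold change -0.54). The first-ranked gene was Ptar1, which encodes a protein with prenyltransferase repeats (chromosome 19, 23687429 to 23731668), with 356.7 ± 70.8 and 206.0 ± 31.4 (log2 fold change -0.78, 95% CI -1.20 to -0.37). The transcriptional repressor Bcl6 (-0.49), the salt-inducible kinase Sik2 (-0.48) and the ubiquitin ligase adaptor Klhl3 (-0.39) were also lower.

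Among those higher in hDISC1AA/+ were Susd2, a membrane protein (493.6 ± 68.1 normalized counts in WT and 706.8 ± 65.5 in hDISC1AA/+; log2 fold change 0.52), and Itga2b, an integrin of platelets (66.8 ± 4.41 and 106 ± 12.7; log2 fold change 0.66). Tnip2, a regulator of NF-kappaB signalling, had 549.3 ± 54.4 and 710.9 ± 27.9 (log2 fold change 0.38). Trim34a (1.02), Ppp1r36 (0.98), Depp1 (1.75) and the transcription factor gene Pax2 (1.58) had low counts, with group means of 55.8 or fewer. The unnamed genes Gm15911 (1.42), ENSMUSG00000086772 (1.56) and Gm26917 (0.89) were the others named by rank. Gm15911 lies antisense to B4galt7, and with no strand information its reads cannot be told from those of that gene. The same holds where Sik2 overlaps Ppp2r1b, Depp1 overlaps Rassf4, Tenm1 overlaps Sh2d1a and Bcl6 overlaps Gm37419, all coding genes on the opposite strand. Trim34a and Pax2 overlap antisense genes, and Fzd3, Stxbp5l and Ppp1r36 overlap a pseudogene or small RNA gene on the opposite strand. Trim34a has close paralogs whose reads the counting could have divided.

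**Figure D2:**
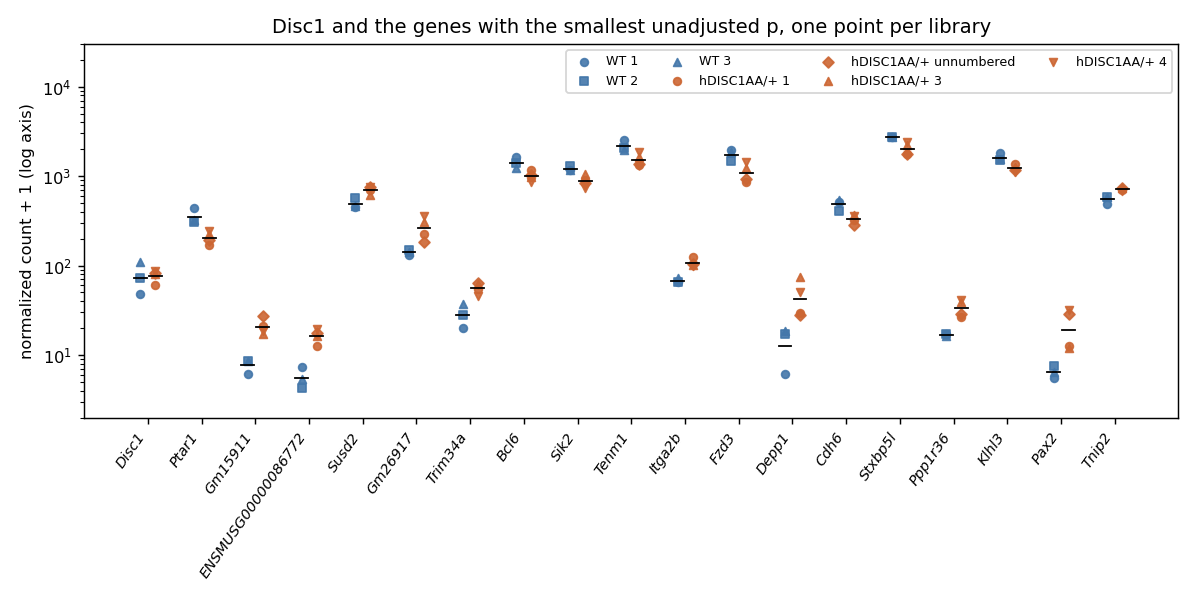
Normalized count + 1 on a log axis for Disc1 and the 18 named genes with the smallest unadjusted p; each point is a library (blue WT, orange hDISC1AA/+) and each black line a group's mean on the log scale. The groups overlap for Disc1 and do not for the other genes, none of which passed the threshold.

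Several lists of neuronal signalling and wiring genes were slightly lower in hDISC1AA/+, by about 0.1 on the log2 scale, and passed with the preset correlation but not with an estimated one. Of 46 measured polarity genes 35 were lower (mean log2 difference -0.11; camera adjusted p = 0.000248 with the preset correlation, adjusted p = 0.235 with an estimated correlation). The polarity members with the smallest p were Dclk1 (log2 fold change -0.31), a doublecortin-like kinase of microtubules, the kinesin gene Kif5c (-0.31) and Apc (-0.36). Of 47 glutamate receptor and scaffold genes 35 were lower (mean -0.11; preset adjusted p = 0.000856, estimated adjusted p = 0.235), with the NMDA receptor subunit genes Grin2a at -0.57 and Grin2d at 0.34 and the scaffold gene Dlg2 at -0.39. The estimated correlation of this list was 0.000523, under the preset 0.01, so a higher correlation does not explain its lost call. Its unadjusted camera p was 0.000238 in the preset form and 0.0071 in the estimated form. Of 56 axon guidance genes 40 were lower (mean -0.09; preset adjusted p = 0.00527, estimated adjusted p = 0.466), led by the Eph receptor genes Epha5 (-0.35) and Epha6 (-0.41) and the netrin receptor gene Unc5c (-0.41). Of 52 potassium channel genes 39 were lower (mean -0.12; preset adjusted p = 0.000791, estimated adjusted p = 0.466), led by Kcna1 (-0.30), Kcnma1 (-0.40) and Kcnn3 (-0.32).

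Of the other neuronal lists some passed with the preset correlation, and none with an estimated one. The list of 35 proteins that act with DISC1 had 27 lower (mean -0.10; preset adjusted p = 0.00409, estimated adjusted p = 0.549). Its members with the smallest p were Pafah1b1 (-0.28), which encodes LIS1, the kinase gene Gsk3b (-0.23; 95% CI -0.50 to 0.03) and Ctnnb1 (-0.25), which encodes beta-catenin. The Wnt and beta-catenin target list, with 15 of 29 members higher, did not pass (adjusted p = 0.896), and neither did Ccnd1 within it (-0.22). Presynaptic vesicle genes (37 of 49 lower, mean -0.11, preset adjusted p = 0.00116), GABA receptor genes (18 of 22 lower, mean -0.16, preset adjusted p = 0.00114), genes with rare loss-of-function variants in schizophrenia (9 of 11 lower, mean -0.17, preset adjusted p = 0.00397) and deep-layer neuron markers (27 of 33 lower, mean -0.17, preset adjusted p = 0.00709) all had adjusted p = 0.549 with an estimated correlation. Perineuronal matrix genes (16 of 25 lower, preset adjusted p = 0.0486) had the same estimated adjusted p of 0.549, and neuropeptide genes (15 of 20 lower, preset adjusted p = 0.049) had an estimated adjusted p of 0.717. No member of any of the 36 lists passed over all genes, and none did adjusted over the list alone; the smallest such value was 0.0943, for Grin2a in the schizophrenia list. In the list means per library, the polarity, axon guidance and presynaptic lists reached the smallest exact permutation p of 0.0286 with an adjusted p of 0.343, and 0 of 36 lists passed. With that smallest p, adjusted over 36 lists, a list could pass only if most lists reached it together. The 0 was therefore nearly fixed in advance and does not speak against a difference. The preset calls of the polarity, glutamate receptor, potassium channel and GABA receptor lists held with each library left out in turn, although the mean of the GABA receptor list was -0.0859 without hDISC1AA/+ replicate 1. Without WT replicate 1 and hDISC1AA/+ replicate 1 together the GABA receptor list lost its call (mean -0.0495, adjusted p = 0.138), and the mean of the polarity list was -0.0561 (adjusted p = 0.00218). Without WT replicate 1 the preset calls of 5 lists were lost and their means shrank or changed sign: DISC1 partners (mean -0.0634, adjusted p = 0.142), presynaptic (-0.0612, 0.107), deep-layer (-0.0431, 0.363), neuropeptide (0.0222, 0.145) and perineuronal (-0.0593, 0.468). That of the schizophrenia list was lost without WT replicate 2 (mean -0.162, adjusted p = 0.0684) and that of the axon guidance list without WT replicate 3 (mean -0.0746, adjusted p = 0.0821). The DISC1 partner list also lost its call without the unnumbered hDISC1AA/+ library (mean -0.0789, adjusted p = 0.0513) and the deep-layer list without WT replicate 2 (mean -0.168, adjusted p = 0.0737). In these 4 omissions, unlike that of WT replicate 1, the mean moved little and the p-value crossed the threshold. Without hDISC1AA/+ replicate 1 the means of the schizophrenia (-0.111) and deep-layer lists (-0.102) were smaller and both passed (adjusted p = 0.0136 and 0.042). Without WT replicate 3 the deep-layer mean was larger in size, at -0.287 (preset adjusted p = 8.26e-05). The neuropeptide list kept its call in 2 of the 7 such tests and the perineuronal list in 1. After correction for GC content and transcript length 2 preset calls were lost. The schizophrenia list went from a mean of -0.172 (standard error over members 0.055) to -0.0616 (0.044), with adjusted p = 0.386, as its mean shrank. The perineuronal list went from -0.12 (0.056) to -0.109 (0.051), with adjusted p = 0.0526, as it lay next to the threshold before. The glutamate and GABA receptor lists passed after it, with smaller means of -0.0568 (adjusted p = 0.0212) and -0.0818 (adjusted p = 0.0413). In the polarity list hDISC1AA/+ replicate 1 lay lowest (-0.17 from the mean of the other 6) and WT replicate 1 highest (0.13).

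Lists of glial and vascular cell types depended mainly on WT replicate 1. Oligodendrocyte genes had 35 of 41 members lower in hDISC1AA/+ (mean -0.32; preset adjusted p = 6.33e-07, estimated adjusted p = 0.549) and astrocyte genes 39 of 41 lower (mean -0.18; preset adjusted p = 1.16e-05, estimated adjusted p = 0.549). Endothelial and mural genes had 36 of 39 members higher (mean 0.36; preset adjusted p = 1.76e-06, estimated adjusted p = 0.549), and meningeal fibroblast genes 30 of 33 higher (mean 0.28; preset adjusted p = 1.16e-05, estimated adjusted p = 0.549). WT replicate 1 deviated from the mean of the other 6 libraries by 0.91 in the oligodendrocyte list, 0.52 in the astrocyte list, -1.24 in the endothelial list and -0.86 in the meningeal list. The oligodendrocyte genes Ermn (1117 normalized counts in WT replicate 1 and 301 to 550 in the other 6) and Ugt8a (1341 and 388 to 658) and the vascular gene Emcn (53.9 and 140 to 214) show it. Without WT replicate 1 the mean differences were -0.026 for oligodendrocytes, -0.011 for astrocytes, -0.062 for endothelial genes and -0.0091 for meningeal genes, and none of these 4 lists passed. Without WT replicate 2, which leaves more weight on WT replicate 1, the oligodendrocyte mean was -0.541 (preset adjusted p = 1.03e-14). Oligodendrocyte precursor genes (15 of 22 lower, preset adjusted p = 0.0381, estimated adjusted p = 0.666) also lost the call without WT replicate 1 (mean 0.0146, adjusted p = 0.888), and without WT replicate 3 (adjusted p = 0.26) or hDISC1AA/+ replicate 4 (adjusted p = 0.219). Their mean was larger in size without WT replicate 2, at -0.218 (preset adjusted p = 6.12e-05). Microglial genes (24 of 34 lower) did not pass (adjusted p = 0.134), but did without WT replicate 2 (mean -0.203, adjusted p = 0.000151) or hDISC1AA/+ replicate 3 (mean -0.11, adjusted p = 0.0211).

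Interferon response genes had 35 of 41 members higher in hDISC1AA/+ (mean 0.31; preset adjusted p = 8.94e-07, estimated adjusted p = 0.549). Ifitm3 (log2 fold change 0.77), Mx1 (0.89) and Oas2 (0.80) had the smallest p. WT replicate 1 lay lowest in this list (-0.76 from the other 6) and the unnumbered hDISC1AA/+ library highest (0.68); without WT replicate 1 the mean difference was 0.08 and the list did not pass (adjusted p = 0.101). Without the unnumbered library the mean was 0.184 and the list passed (adjusted p = 0.000991). Peripheral immune genes had 13 of 17 members higher (mean 0.33; preset adjusted p = 0.0145, estimated adjusted p = 0.549), with hDISC1AA/+ replicate 1 at 1.22; without hDISC1AA/+ replicate 1 the mean difference was 0.05 (adjusted p = 0.289), and the call was also lost without WT replicate 1 (mean 0.0556, adjusted p = 0.48) or WT replicate 2 (adjusted p = 0.0684, with the mean nearly unchanged at 0.324). Blood genes (6 of 10 higher, adjusted p = 0.182; 0.00083 without WT replicate 3 and 0.00495 without hDISC1AA/+ replicate 3) varied within both groups, from 501 to 6777 normalized counts for Hba-a1.

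Mitochondrially encoded genes had all 12 measured members lower in hDISC1AA/+ (mean -1.08; preset adjusted p = 0.000159, estimated adjusted p = 0.549). hDISC1AA/+ replicate 1 deviated by -3.39 and WT replicate 1 by 1.76. These means weigh all members alike, and the members differed widely. In hDISC1AA/+ replicate 1 mt-Nd3 had 0 normalized counts (199.4 to 1105.8 in the other libraries), while mt-Nd5 had 92050 (152273 to 297298 in the others). The mean of -1.08 came largely from hDISC1AA/+ replicate 1 and WT replicate 1: it was -0.27 without hDISC1AA/+ replicate 1 (adjusted p = 0.042) and -0.64 without WT replicate 1, when the list did not pass (adjusted p = 0.0579). Without both libraries the mean difference was 0.18, in the opposite direction (preset adjusted p = 0.000948, estimated adjusted p = 0.568). Nuclear genes of oxidative phosphorylation had 63 of 75 members lower (mean -0.07; preset adjusted p = 0.0287, estimated adjusted p = 0.835); without WT replicate 1, which deviated by 0.49, their mean difference was 0.13 and passed in the opposite direction (adjusted p = 8.64e-14), and without hDISC1AA/+ replicate 3 or 4 the list did not pass (adjusted p = 0.313 and 0.219). Heat shock and unfolded protein response genes had 32 of 39 members lower (mean -0.09; preset adjusted p = 0.000159, estimated adjusted p = 0.492), led by the endoplasmic reticulum chaperone genes Dnajc3 (-0.36), Hsp90b1 (-0.43) and Pdia3 (-0.24). This list kept its preset call with each library left out in turn. Immediate early genes had 32 of 41 members lower (mean -0.13; preset adjusted p = 0.0238, estimated adjusted p = 0.717), with the phosphatase genes Dusp4 (-0.52) and Dusp6 (-0.41) and the transcription factor gene Crem (-0.45) first; the mean difference was 0.06 without WT replicate 1 and 0.0088 without the unnumbered hDISC1AA/+ library, and the list did not pass without hDISC1AA/+ replicate 1 (adjusted p = 0.073).

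The other lists did not pass with the preset correlation. These were the glucocorticoid response (adjusted p = 0.054), choroid plexus (0.122), thalamic (0.179), monoamine signalling (0.218), olfactory bulb (0.259), upper-layer neuron (0.641), striatal (0.668), ribosomal protein (0.779), inhibitory neuron (0.901) and circadian clock lists (0.992). Mean, median and test differed in sign for 3 of them, all with near-zero means: the upper-layer list (median 0.04), the inhibitory neuron list (mean -0.02, median 0.03) and the circadian list (median -0.006). Of the 14 lists that did not pass, 8 passed with the preset correlation in at least 1 alternative. The ribosomal protein list did so in both directions: higher without WT replicate 1 (mean 0.18, adjusted p = 1.52e-27) and lower without WT replicate 2 (-0.222, 2.18e-07) or WT replicate 3 (-0.114, 0.0453). The circadian list was lower without WT replicate 1 (-0.131, 0.0292). The olfactory bulb (0.699, 1.22e-07) and inhibitory neuron lists (0.129, 0.0138) were higher without hDISC1AA/+ replicate 1. The glucocorticoid list was lower without WT replicate 2 (-0.266, 0.000568), WT replicate 3 (-0.182, 0.0331), hDISC1AA/+ replicate 1 (-0.141, 0.0376) or hDISC1AA/+ replicate 3 (-0.191, 0.00656). The choroid plexus list was higher without WT replicate 3 (0.331, 0.026) or the unnumbered library (0.271, 0.0366). In each pair of values the mean difference comes first and the adjusted p next. Splits of the 7 libraries other than that by genotype passed 10 to 22 of the 36 lists with the preset correlation. With an estimated correlation 0 lists passed in every split, the one by genotype included. In all, 22 of 36 lists passed camera with the preset correlation (4 higher, 18 lower), 0 passed with an estimated correlation and 0 passed fry. Without WT replicate 1 the count was 10, and 7 of the 22 kept their direction and call. Without WT replicate 1 and hDISC1AA/+ replicate 1 together it was 15, and 9 of the 22 kept their direction and call: the polarity, glutamate receptor, axon guidance, potassium channel, presynaptic, DISC1 partner, schizophrenia, heat shock and interferon lists. Of these, the means of the polarity (-0.0561), presynaptic (-0.0642), DISC1 partner (-0.0589) and interferon lists (0.151) shrank by more than 1.5 times, and none of the 9 passed with an estimated correlation (adjusted p of 0.568 or more).

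**Figure D3:**
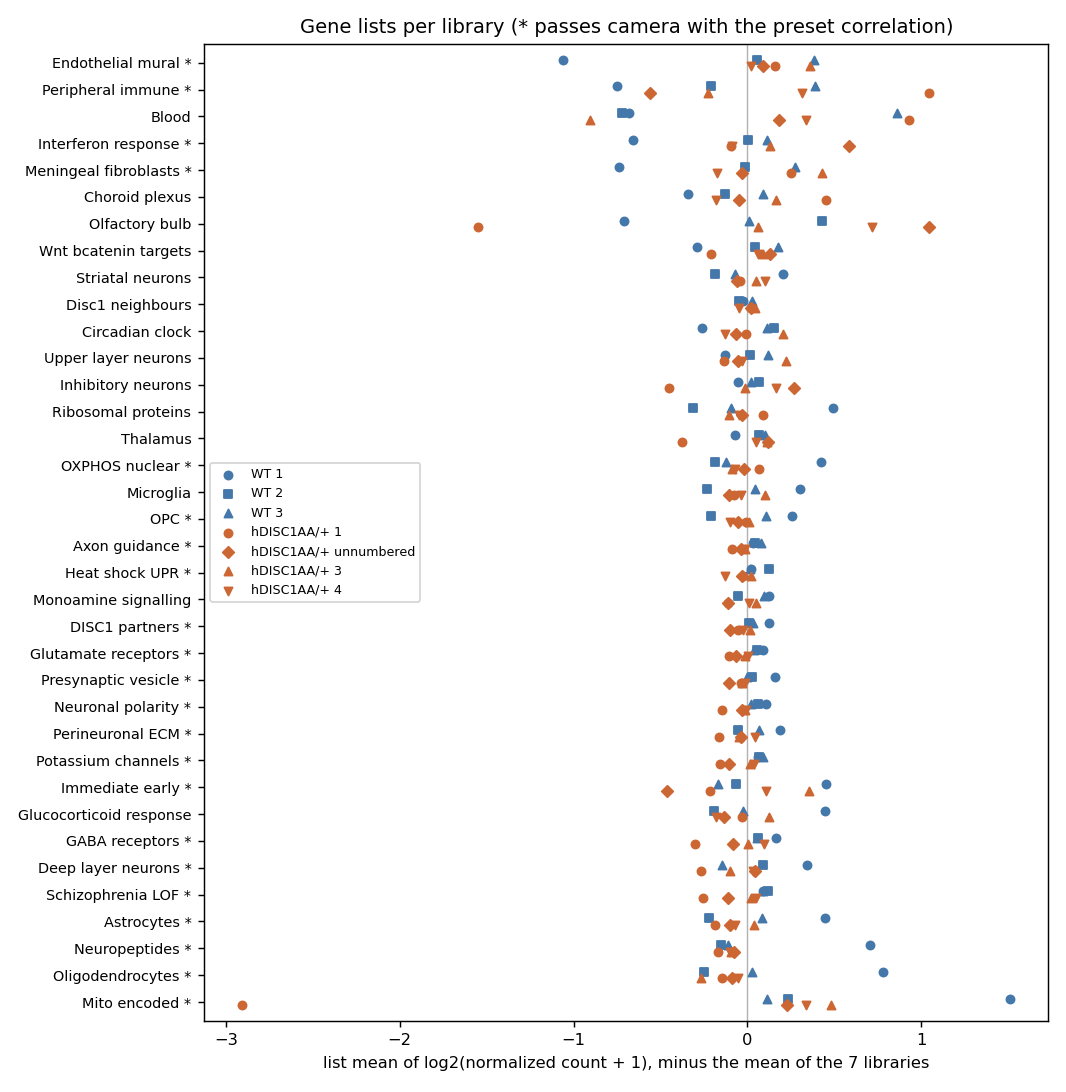
Each row is a gene list and each point a library (blue WT, orange hDISC1AA/+); the horizontal axis is the list's mean log2(normalized count + 1) minus the mean of the 7 libraries, and a star marks lists that passed camera with the preset correlation. WT replicate 1 and hDISC1AA/+ replicate 1 hold most of the extreme positions, while the neuronal lists near the middle differ by about 0.1.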

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

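Of 59 values tested in the 4 hDISC1AA/+ libraries (Disc1, the named genes, the list means and 4 library measures), 2 had 1 library farther from the others than Dixon's 95% limit for 4 samples allows, where chance gives about 1 in 20. Both were set by hDISC1AA/+ replicate 1. In the mean of the mitochondrially encoded genes, its gap to the next library was 0.927 of the group's range. In the mean of the thalamic list it was 0.863. Of the tests below, the correction for GC content and length and the comparison of the olfactory list with other tissues were chosen only after the result was seen.

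hDISC1AA/+ replicate 1 stood apart in other ways too. Trends with GC content and transcript length accounted for 0.358 of the variance of its deviations, the most of the 7 libraries, with genes of high GC content reading higher (Spearman's rho across genes 0.609; genes are not independent replicates). This is consistent with a technical difference in RNA or library quality for part of the pattern. Its olfactory bulb genes were low (-1.81 from the mean of the other 6). After correction for GC content and length they were still at -1.95 with a spread of 0.62 among the others, which argues against those trends as the cause. The larger of its striatal and thalamic deviations was 0.438 in size, and it was that of the thalamic list, which also lay apart in this library. Whether the dissected piece held less olfactory bulb therefore stays open; no biological explanation was tested, since the other 3 hDISC1AA/+ libraries do not share the pattern.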

How the results depend on the processing

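The count of genes was 0 in all 26 alternatives, and the 18 named genes kept their direction and stayed short of the threshold in all 427 values computed. Their kept direction is no support, since they were chosen by the smallest p in the same data. The 22 lists depended on the form of the camera test (preset or estimated correlation) and on single libraries, WT replicate 1 most of all. Without it 7 of the 22 kept direction and call, and without each of the other libraries 18 or 19 did. With the CPM filter 18 kept both, and after GC and length correction 20 (the schizophrenia and perineuronal lists lost the call). The count was 0 with an estimated correlation, with fry, and with an estimated correlation either after GC and length correction or without WT replicate 1 and hDISC1AA/+ replicate 1 together. It ranged from 10 to 23 when single libraries were left out (10 without WT replicate 1) and from 15 to 23 in the other alternatives. Of the 14 lists that did not pass, 8 did with the preset correlation in at least 1 alternative, among them the glucocorticoid, ribosomal protein and microglial lists after GC and length correction (lower, adjusted p = 0.0114, 0.0116 and 0.0413). Without WT replicate 1 and hDISC1AA/+ replicate 1 together the ribosomal protein (0.142), olfactory bulb (0.388), inhibitory neuron (0.0959) and circadian lists (-0.127) passed. With each library left out in turn, 5 of the 22 lists kept direction and call throughout. List levels per library passed in 0 of 36 lists in all 3 ways of summarising them, which the smallest possible permutation p made nearly certain beforehand. Disc1 ranged from -0.218 to 0.382 with single libraries left out, and changed sign without WT replicate 1 and hDISC1AA/+ replicate 1 together (-0.108), with voom quality weights (-0.243), with array weights (-0.3) and with 1 surrogate variable (-0.153). The array weights rested the WT side mostly on WT replicate 3, the library with the highest Disc1 (109). The direction of the test changed without WT replicate 1 in the astrocyte (-0.344 to -0.0114 over single libraries left out, where the mean stayed below 0), endothelial (-0.0619 to 0.659), immediate early (-0.263 to 0.0622; also without the unnumbered library, 0.00878), meningeal (-0.00913 to 0.495), neuropeptide (-0.405 to 0.0222) and oxidative phosphorylation lists (-0.179 to 0.126). Without both libraries, under either correlation, the differences were 0.0237 for astrocyte, -0.0621 for endothelial, 0.115 for immediate early, -0.0539 for meningeal, 0.176 for mitochondrially encoded, 0.0414 for neuropeptide, 0.0948 for oxidative phosphorylation and -0.216 for peripheral immune genes. The mean, though not the test, also changed sign for oligodendrocyte precursor genes without WT replicate 1 (0.0146) and without both (0.00527), and for deep-layer genes without both (0.0212). The cause was not tested beyond the libraries left out. At 33512557 reads or more per library, how far depth limits genes of few reads was not tested. Simulated 1.5-fold changes were called for 13.4% of 67 genes, all above a minimum mean count, so this share does not cover genes of few reads.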

Other observations

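Several transcripts of neighbouring tissues and of immune cells differed between libraries of the same genotype. The genes named in this part, the correction for GC content and length, the removal of 2 libraries together and the test on dissection were chosen only after the result was seen. The olfactory bulb genes Tbx21, Eomes and Cdhr1 were highest in the unnumbered hDISC1AA/+ library (414, 1235 and 5138 normalized counts) and lowest in hDISC1AA/+ replicate 1 (7.4, 88.8 and 509.8). WT replicate 1 was the next lowest (12.2, 114.9 and 968.5). Ttr, an abundant transcript of the choroid plexus, had 758 normalized counts in hDISC1AA/+ replicate 1 and 14.2 to 41.5 in the other 6. The pituitary hormone genes Gh and Prl had 0 in the 3 WT libraries and in hDISC1AA/+ replicate 1, and 8.2 to 58.5 (Gh) and 2.1 to 7.6 (Prl) in the other 3 hDISC1AA/+ libraries. The neutrophil genes S100a9 and Ngp were highest in hDISC1AA/+ replicate 1 (259 and 208) and replicate 4 (123 and 133). In the unnumbered hDISC1AA/+ library, the interferon-induced genes Irf7 and Oasl2 had 195 and 291 normalized counts, against 32.7 to 96.4 and 76.4 to 170 in the other 6.

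WT replicate 1 stood apart from the other 6 libraries by cell type markers and by its processed pseudogenes. With all libraries thinned to the same depth its oligodendrocyte list still deviated by 0.897 and its vascular list by -1.28. Thinning keeps each gene's expected share of the reads, so for genes of many reads this outcome was nearly fixed in advance. It speaks only to the number of reads, and not to other differences that may have come with the depth. After correction for GC content and length the deviations were 0.888 and -1.25. It had the highest value of the 7 for 90.2% of the oligodendrocyte genes and the lowest for 84.6% of the vascular genes, where chance gives 14.3%. These shares restate the deviations of the lists and speak for no cause. A dissected piece with more myelinated tissue and fewer vessels stays open, and so does a difference in sequencing or read assignment, which was not tested. The title of this library has another form than the names of the other 6, so another batch is not ruled out, and among genes with a mean of at least 50 normalized counts 34.8% of 293 processed pseudogenes deviated by more than 1 on the log2 scale in this library, against 3.75% to 11.9% in the others.

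The normalized counts of single genes also differed widely between libraries. Gm7336, a processed pseudogene, had 11.6 normalized counts in WT replicate 1 and 3260 to 4429 in the other 6, while Rpl35 had 1807 and 226 to 347. Gapdh, often used as a reference gene, had 5593 normalized counts in WT replicate 1 and 4582 in hDISC1AA/+ replicate 4, but 447 to 1202 in the other 5, whereas Actb stayed between 29116 and 35381. These values are assigned reads and do not by themselves show that the expression of Gapdh differed between samples. The treatment of reads that match several places is not given in the sources used here, and its part in these values was not tested.

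All lists together were weighed against chance, by counting those that passed in either direction in each split of the libraries. The slightly lower neuronal lists were not counted apart in the splits. They were weighed against the trends with GC content and length and against the same 2 libraries. Of the 35 ways to divide the libraries into 3 and 4, the real one included, 2 gave 22 lists or more (22 in the real one and 22 in the highest of the others). The other splits all passed lists with the preset correlation, from 10 to 22 of them. A preset call alone therefore does not speak for a difference by genotype. With an estimated correlation 0 lists passed in all 35 splits, so that form told no grouping of the libraries apart. As for genes, 21 of the 35, again with the real one, gave as many at an unadjusted p under 0.05 (431 in the real one, with 2184 the highest of the others), so chance can be excluded for neither. The split with the most genes joined both libraries that stand apart with WT replicate 3, and 0 genes passed the threshold in it. It was picked afterwards as the highest of the 35, and whether it reflects a structure of the samples was not tested. Over 7 lists (polarity, axon guidance, potassium channels, glutamate and GABA receptors, presynaptic and DISC1 partners) the median of the mean differences was -0.11. It was -0.082 (standard error 0.04) after correction for GC content and length, and -0.064 (standard error 0.026) without WT replicate 1 and hDISC1AA/+ replicate 1 together. With spreads of this size, neither the trends nor the 2 libraries can be told apart from an effect of genotype of under 0.1 on the log2 scale, which stays a hypothesis for more animals.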
